A study of Mus musculus with 7 samples.

How the data were processed

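Gene expression was measured on 7 Affymetrix arrays, each hybridised with biotin-labelled total RNA from macrophages sorted by flow cytometry from the colonic lamina propria of C57BL/6 mice aged 6 weeks. The deposited values are on the log2 scale and run from 3.55 to 14.8 with no missing value. The submitters' processing notes name RMA, a method that corrects background, normalizes and summarises the probes of a set, and Partek, an analysis program. Their versions, the genome build and whether all arrays were normalized together are not given in the sources used here. The quartiles of the deposited log2 values were alike within each sort label and differed between the sort labels. The upper quartile was 8.26 and 8.30 in the CX3CR1hi arrays and 7.93 to 8.01 in the resident arrays. RMA pulls low values together, so a fold change of a dim gene is smaller on this scale than the change in its RNA. Probe sets of close paralogues can share signal, and the number of arrays limits the precision of every value.

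Samples were grouped by the genotype in their labels. WT (4 arrays) stands for mice carrying 1 Cx3cr1 allele replaced by GFP. Il10_KO (1 array) stands for Il10-deficient mice with the same reporter, and Il10ra_mKO (2 arrays) for mice in which Cre recombinase expressed from Cx3cr1 deletes Il10ra. By their labels WT and Il10ra_mKO also differ in the Cx3cr1 allele, GFP against Cre. No array carries Cre without the Il10ra deletion, so effects of the allele and of the deletion cannot be told apart. WT array 1 and the Il10_KO array carry the sort label CX3CR1hi, and WT arrays 2, 3 and 4 and both Il10ra_mKO arrays carry the label resident. The extraction protocol names miRNeasy Mini kits for samples 1 and 2 and RNeasy Micro kits for the others. As far as it numbers the samples in the order of the series, the kit follows the sort label, so label, kit and array batch cannot be told apart. Replicate numbers were given in accession order and only name the arrays. The labels do not say whether arrays of 1 group came from separate animals, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values.

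The table has 35399 rows. The probe table pairs 21789 rows with exactly 1 gene symbol, 1621 with several and 11989 with none. Of the rows with 1 symbol, 21698 were matched by gene ID to the RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols, and 91 were not matched. For the 999 genes with several rows the row with the highest mean over the 7 arrays was kept, which left 19938 genes. No filter on brightness was applied in the main analysis. A brightness filter served as an alternative and kept the 10558 genes above log2 5.86, the median of all values, in at least 2 arrays.

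Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on expression), with group and sort label in the model and all 7 arrays in the fit. With the sort label in the model, Il10ra_mKO (2 arrays) is set against the 3 resident WT arrays, and the Il10_KO array against the CX3CR1hi WT array. The Il10_KO array and its WT partner are assumed to vary as the arrays of the other groups do. The fit has 3 residual degrees of freedom and an estimated prior of 0.831. P-values are two-sided and were adjusted over the genes tested by Benjamini-Hochberg. A gene passed at an adjusted p under 0.05. The difference between both mutant effects was tested as a contrast of its own.

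Gene lists were tested with camera (limma, preset correlation between genes of 0.01), adjusted over the 20 gene lists or the 12 cell type marker lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, served as alternatives. Of the 368 places in the gene lists 340 were measured, and of the 168 in the marker lists 150. Within a list, gene p-values were also adjusted over the list alone. The score of a marker list in an array is the mean log2 value of its measured genes. Lists, tests, groups, alternatives and the rule for named genes were fixed before the data were examined.

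The rule named Il10ra and Il10. It named the 10 genes with the largest change in each direction for Il10ra_mKO against WT whose mutant arrays both lay outside the range of the resident WT arrays. It named 6 in each direction for Il10_KO against WT whose mutant array lay outside the range of the 4 WT arrays, and 5 in each direction for the difference of the effects. All had to pass the threshold, and where fewer passed the places were filled with the smallest p in that direction. It also named 3 members of each list past its test, 1 member of each other gene list, and the highest member of each marker list. Predicted genes, genes named after clones, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors, and antigen receptor segments were left out of these choices. Genes named outside this rule are marked as chosen after their values were seen.

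The alternatives left the sort label out, used it as a random block, dropped the variance trend, made the variance estimate robust, filtered dim genes, quantile-normalized or median-centred the arrays, averaged the rows of a gene or used every row, changed the threshold, used the resident arrays alone, used runs of sample numbers as a block, or left out each array in turn. Chosen after seeing the data were a filter that drops the 1640 genes (8.23% of those tested) whose 5 resident values lie within 0.02, the brightness filter together with an unadjusted p under 0.05 and a change of at least 2-fold, and 9 alternatives for the comparison of the sort labels (the brightness filter, quantile normalization, median centring and leaving out each of 6 arrays). The test of the lists on the difference of the effects was also added later.

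The code was tested on simulated data in which 100 of the 19938 genes were changed by 1 and 100 by 2 on the log2 scale. For the Il10ra comparison, 59% of the genes changed by 1 and 78% of those changed by 2 passed, with 8 false calls. By an unadjusted p under 0.05 with a change of at least 2-fold, 56% and 100% passed, with 23 false calls. For the Il10 comparison the adjusted test found 48% and 69% with 3 false calls, and the second criterion found 44% and 96% with 85 false calls. A shifted list was found in both comparisons, and 0 of the other lists was called. Relations across genes were set beside 100 simulated data sets without effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Rows without exactly 1 gene symbol were left out of the comparisons.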

Results

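The series holds 7 arrays of macrophages sorted from the colonic lamina propria, the layer beneath the gut epithelium in which resident macrophages lie. IL-10 is a cytokine that restrains inflammatory gene expression, and its receptor pairs the ligand-binding chain Il10ra with Il10rb. The comparisons ask how colonic macrophages change when they lack Il10ra and when mice lack IL-10, and whether both changes differ. WT comprised 4 arrays, Il10_KO 1 array and Il10ra_mKO, the macrophage-restricted Il10ra deletion, 2 arrays. The labels call the cells of WT array 1 and of the Il10_KO array CX3CR1hi and those of the other 5 arrays resident. CX3CR1 is the receptor for fractalkine and is abundant on resident gut macrophages. Median expression lay between log2 5.77 and 5.92 in the 7 arrays. Arrays of the same sort label correlated across genes at a Pearson r of 0.976 to 0.991, and arrays of different sort labels at 0.917 to 0.934. The first principal component held 51.4% of the variance and set the CX3CR1hi arrays (42.4 and 47.8) apart from the resident ones (-24.3 to -10.9). The second held 31.2%, with the 4 WT arrays between 12.4 and 28.2 and all 3 mutant arrays below 0.

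Il10ra stood at log2 10.81 ± 0.28 (SD, n = 3) in the resident WT arrays and at 8.05 and 7.04 in the Il10ra_mKO arrays. It fell by 3.27 ± 0.38 on the log2 scale (SE), a 9.63-fold decrease. Its adjusted p was 0.243 over all genes tested and 0.0074 adjusted over the list alone, here the 6 measured genes of the IL-10 receptor pathway. In the CX3CR1hi arrays Il10ra was at 11.32 in WT and 11.61 in the array labelled Il10-deficient. The Il10 transcript was at 11.04 in the CX3CR1hi WT array and at 10.75 in the array labelled Il10-deficient, a difference of -0.28 ± 0.64 (SE, adjusted p = 0.849). In the resident arrays Il10 was at 9.76, 9.83 and 10.86 in WT and at 10.21 and 10.43 in Il10ra_mKO. Where the Il10 probes lie relative to the deleted part is not given in the sources used here, so this level checks nothing. Every direction given below for this genotype rests on the label alone.

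**Figure D1:**
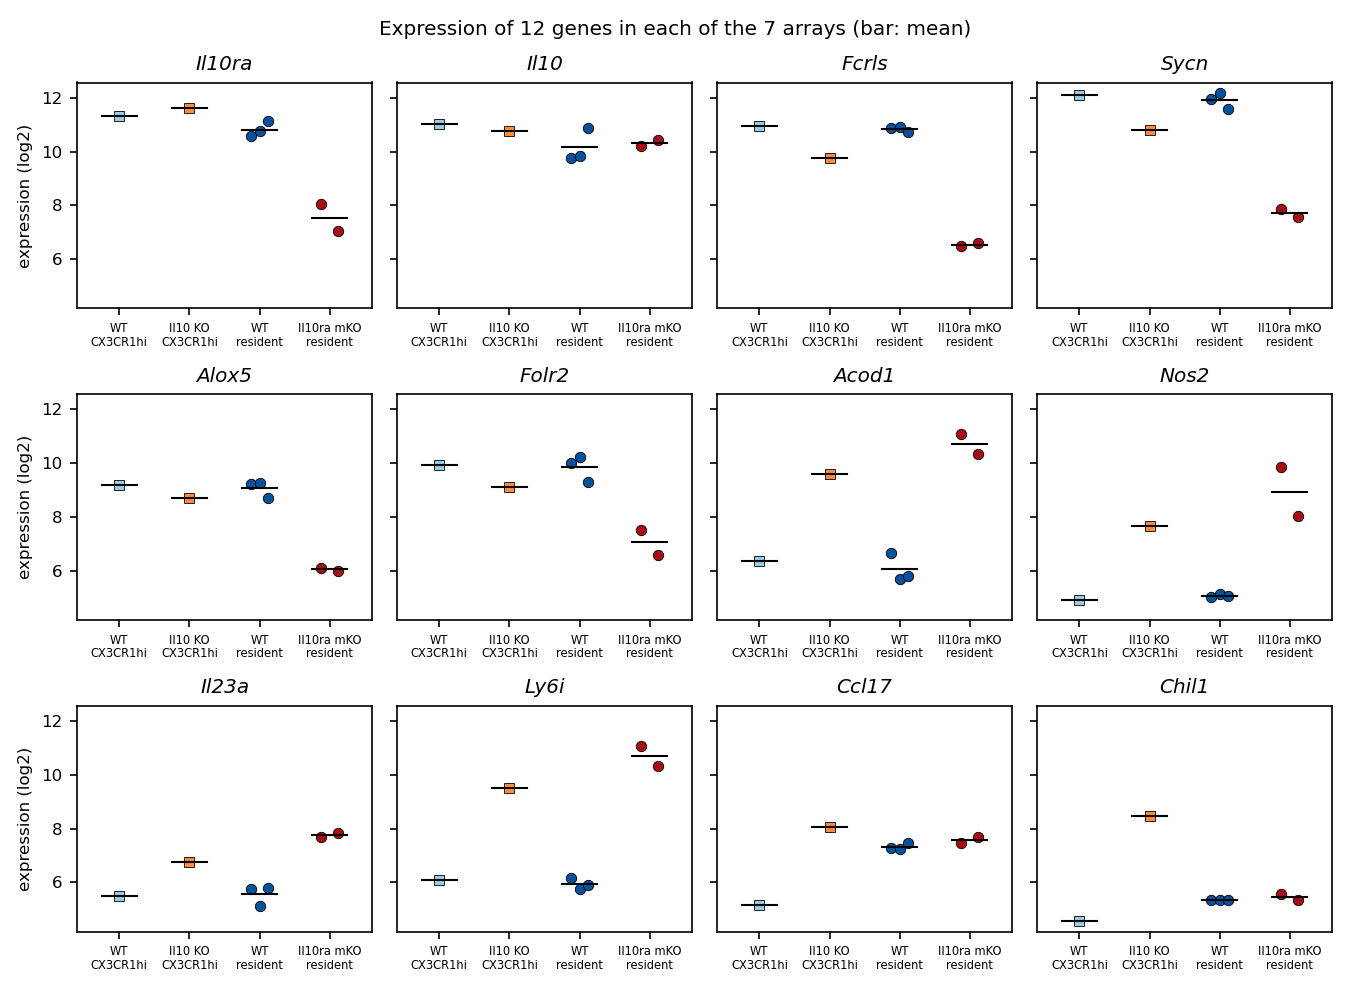
Expression (log2) of 12 named genes in each of the 7 arrays, with squares for the CX3CR1hi and circles for the resident arrays, and a bar at the mean of each group. Il10ra lies at 8.05 and 7.04 in the Il10ra_mKO arrays and between 10.56 and 11.61 in the others, and Ccl17 and Chil1 are lowest in the CX3CR1hi WT array (5.18 and 4.56).

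In the sorted cells, interferon-response and antimicrobial genes had more RNA in Il10ra_mKO than in WT of the same sort label by camera. With an estimated correlation these lists did not pass (adjusted p = 0.187 for the interferon-gamma and the antimicrobial list and 0.421 for the type I interferon list). Marker lists moved as well by camera, with medians of 1.22 for monocytes, -0.87 for epithelium and -0.78 for fibroblasts and muscle. With an estimated correlation they did not pass either (adjusted p = 0.347, 0.494 and 0.347). The monocyte median was 0.61 without Il10ra_mKO array 1, and the epithelial median -0.21 without Il10ra_mKO array 2. Acod1, which makes the antimicrobial metabolite itaconate in activated macrophages, rose 25.2-fold (log2 4.65 ± 0.43, SE, 2 against 3 arrays), Saa3, an acute-phase protein, 16.5-fold and Nos2, the inducible nitric oxide synthase, 14.5-fold, each adjusted over the list alone (adjusted p = 0.00847, 0.0208 and 0.0208). In resident WT Saa3 lay at 5.19 to 5.68 and Nos2 at 5.03 to 5.13, under the brightness cut of log2 5.86, so both folds start near the floor. The Il10ra_mKO arrays were apart, at 10.62 and 8.38 for Saa3 and at 9.86 and 8.03 for Nos2. The mean level of epithelial markers was apart in them too, at 10.4 and 8.52. Which of the sorted cells carried these transcripts was not tested. Without array 1 the log2 change was 2.92 for Saa3 and 2.95 for Nos2, and without array 2 it was 5.16 and 4.78. Il23a, a subunit of the cytokine IL-23, rose 4.63-fold, and Il12b, the p40 chain that IL-12 and IL-23 share, rose 3.80-fold, adjusted over the list alone (adjusted p = 0.0102 and 0.00555). Fcrls, a scavenger receptor-like gene of resident macrophages, fell 19.6-fold (log2 -4.29 ± 0.076) and was the only gene to pass over all genes tested (adjusted p = 0.0194). Its level was 10.83 ± 0.090 (SD, n = 3) in WT and 6.49 and 6.59 in Il10ra_mKO. Fcrls did not pass with runs of neighbouring sample numbers as a block (adjusted p = 0.213) or when any of the resident WT arrays was left out (adjusted p of 0.269 to 0.553). Over 21 alternatives its change lay between -4.34 and -4.25, with adjusted p from 1.1e-05 to 0.553.

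By limma over 19938 genes, 0 genes rose and 1 fell. At an unadjusted p under 0.05, 810 genes were higher and 770 lower, together 7.92% of the genes tested. With a change of at least 2-fold besides, 154 were higher and 212 lower, a criterion fixed beforehand, with which simulated data gave 23 false calls. The 10 higher genes with the smallest p did not pass, with adjusted p from 0.0617 for Lmo4 to 0.143 for F10. The largest among them was Ly6i, a member of the Ly6 surface protein family, which was 26.9-fold higher (log2 4.75 ± 0.28, adjusted p = 0.123). F10, coagulation factor X, was 8.70-fold higher, Cd300lf, an inhibitory receptor of myeloid cells, 8.21-fold, complement factor B (Cfb) 6.17-fold and Il18bp, which binds and blocks IL-18, 4.02-fold. Ikbke, a kinase of innate signalling, was 2.49-fold higher, the transcriptional regulator Lmo4 2.21-fold, Tap2, a peptide transporter of antigen presentation, 2.06-fold, Casp12 1.81-fold and Socs1, a feedback inhibitor of cytokine signalling, 1.64-fold. The 9 lower genes after Fcrls did not pass either, with adjusted p from 0.0617 to 0.143. Sycn, which encodes the secretory granule protein syncollin, was 18.2-fold lower (log2 -4.19 ± 0.22) and Nxpe2 13.2-fold lower. The sulfotransferase genes Sult1c2 and Sult1a1 were 4.66-fold and 3.16-fold lower, and the drug efflux pump gene Abcb1a and the glycosyltransferase gene B3gnt7 both 3.19-fold. Reps2, Fah and Fthl17f were 2.03-fold, 1.32-fold and 1.11-fold lower, and Socs1, Fah and Fthl17f lay below the brightness filter.

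Of the 20 gene lists, 12 rose and 1 fell by camera. The interferon-gamma response had the largest median change of these lists, 1.20 (adjusted p = 7.9e-18, and adjusted p = 0.187 with an estimated correlation), and a mean of 1.34 against 1.49 in the antimicrobial list. All 14 measured members were higher, and 13 rose adjusted over the list alone. Gbp5 and Iigp1, GTPases that act against intracellular microbes, rose by 2.29 ± 0.26 and 2.29 ± 0.29 on the log2 scale, and Nlrc5, an activator of MHC class I genes, by 2.09 ± 0.26, adjusted over the list alone. The antimicrobial and oxidative defence list rose with a median of 0.75 (adjusted p = 1.25e-09; 6 of 16 members, adjusted over the list alone). The inflammatory cytokines rose with a median of 0.60 (adjusted p = 4.87e-08; 3 of 19 members, adjusted over the list alone), and 0.36 without WT array 3. Inhba, which encodes the activin A subunit, was 3.09 ± 0.75 higher without passing over its list, at 9.49 and 7.22 against 5.23 to 5.29 in WT. With an estimated correlation the adjusted p of these 3 lists was 0.187, and fry gave adjusted p = 0.0249 to 0.0285.

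The other lists that rose by camera did not pass with an estimated correlation or by fry. Glycolysis and hypoxia rose with a median of 0.74 (5 of 17 members, adjusted over the list alone; adjusted p = 2.71e-08, and adjusted p = 0.344 with an estimated correlation). The lactate exporter Slc16a3 rose by 1.73 ± 0.24 and the glucose transporter Slc2a1 by 1.21 ± 0.26, adjusted over the list alone, and the angiogenic factor Vegfa was 1.94 ± 0.63 higher without passing. The type I interferon response rose with a median of 0.58 (4 of 19 members, adjusted over the list alone; adjusted p = 4.37e-08, and adjusted p = 0.421 with an estimated correlation), led by Rsad2, an antiviral enzyme (1.40 ± 0.28), and Irf7, an interferon regulator (1.09 ± 0.19). Ifit2 was 1.08 ± 0.44 higher without passing. Pattern recognition and inflammasome genes rose with a median of 0.30 (adjusted p = 1.87e-05; 2 of 20 members, adjusted over the list alone), with the bacterial sensor Nod1 1.40 ± 0.11 up. Tlr2 and Nod2 were 1.02 ± 0.25 and 0.91 ± 0.20 higher without passing. Chemokines rose with a median of 0.23 (adjusted p = 0.00819; 2 of 23 members, adjusted over the list alone). Ccl5, which attracts T cells, rose by 2.96 ± 0.27 and Cxcl9, an interferon-induced chemokine, by 1.86 ± 0.25, adjusted over the list alone, while Ccl22 was 1.05 ± 0.29 higher without passing. With an estimated correlation the pattern recognition and chemokine lists both had adjusted p = 0.421. The chemokine list was lost by camera with the brightness filter (adjusted p = 0.0595). Its median was 0.07 without Il10ra_mKO array 2 and 0.05 without WT array 3. The pattern recognition median was 0.47 without Il10ra_mKO array 1 and 0.13 without array 2, and the glycolysis median was 0.49 without array 1.

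Costimulation and coinhibition rose with a median of 0.37 (adjusted p = 0.00493; 1 of 11 members, adjusted over the list alone). That member was Pdcd1lg2, a ligand of PD-1 (2.20 ± 0.35), while Cd274, the other PD-1 ligand, was 1.45 ± 0.47 higher and Tnfsf9 0.93 ± 0.52 higher without passing. No member passed adjusted over the list alone in the remaining called lists. The NF-kB list had a median of 0.32 (adjusted p = 2.69e-05; 16 of 16 members higher), with Clec4e, a receptor for mycobacterial lipid, at 3.21 ± 0.88, Tnfaip2 at 1.36 ± 0.40 and Traf1 at 0.87 ± 0.25. MHC class II presentation had a median of 0.26 (adjusted p = 0.000147; 10 of 10 members higher), with H2-Oa at 1.49 ± 0.44, Ciita, the activator of MHC class II genes, at 0.64 ± 0.22 and Ifi30 at 0.47 ± 0.12. With an estimated correlation these 3 lists had adjusted p = 0.421. The IL-10 induced genes had a median of 0.33 (adjusted p = 0.000619, and adjusted p = 0.344 with an estimated correlation). Nfil3, Ddit4 and Il1rn, the IL-1 receptor antagonist, were 1.49 ± 0.59, 1.44 ± 0.26 and 1.00 ± 0.28 higher in it. The lysosome list had a median of 0.17 (adjusted p = 0.00196, and adjusted p = 0.547 with an estimated correlation), with the proteases Ctsd at 0.44 ± 0.16 and Ctsz at 0.38 ± 0.15 and the lipase Lipa at 0.39 ± 0.29. Oxidative phosphorylation fell with a median of -0.23 (adjusted p = 0.00196; 14 of 16 members lower), led by the complex III subunits Uqcrc1 (-0.31 ± 0.20) and Uqcrc2 (-0.29 ± 0.18) and by Atp5a1 (-0.27 ± 0.13). With an estimated correlation its adjusted p was 0.577.

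The size of several of these changes rested on Il10ra_mKO array 2. Leaving out either Il10ra_mKO array leaves 1 mutant array, with the spread from the WT arrays alone, so only medians are given for it. Without array 2 the median was -0.06 for oxidative phosphorylation, with Uqcrc1 and Uqcrc2 also at -0.06. It was 0.16 for costimulation, 0.13 for MHC class II, 0.04 for the lysosome list (camera pointing down) and 0.555 for the IL-10 induced genes. With array 1 left out the medians were 0.58 for costimulation, 0.43 for MHC class II and 0.275 for the lysosome. Leaving out WT array 3 gave 0.20 for the NF-kB list and -0.15 for oxidative phosphorylation, and leaving out WT array 4 gave 0.67 for costimulation, all past the threshold.

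The other 7 lists were not called with all arrays. Resident intestinal macrophage identity had a median of -0.13 (adjusted p = 0.123), and 2 of its 23 members fell adjusted over the list alone. They were the folate receptor gene Folr2, 6.93-fold lower (log2 -2.79 ± 0.44), and Hpgd, which inactivates prostaglandins (-1.51 ± 0.22). Scavenging and efferocytosis had a median of -0.03 (adjusted p = 0.0902), with 1 of 22 members fallen adjusted over the list alone, Gas6, a bridge to dying cells (-1.75 ± 0.20). Cd209a, a lectin, was at -2.22 ± 0.42 on the log2 scale, at 6.47 and 7.16 against 8.63 to 9.65 in WT, without passing. In eicosanoid metabolism the median (0.17) and the mean (-0.21) differed in sign and camera gave adjusted p = 0.928. Adjusted over that list alone 1 member rose and 3 fell, among them Alox5, the 5-lipoxygenase of leukotriene synthesis (8.07-fold, log2 -3.01 ± 0.22), and Ltc4s, which makes leukotriene C4 (-1.79 ± 0.21). Hpgd, Gas6 and Ltc4s were chosen after their values were seen. The median was 0.10 for the IL-10 receptor pathway (mean -0.44, adjusted p = 0.975), 0.24 for matrix remodelling and growth factors (adjusted p = 0.614), -0.07 for the cell cycle (adjusted p = 0.104) and 0.06 for immediate early and heat shock genes (adjusted p = 0.928). Some of these lists passed by camera when a WT array was left out. They were scavenging without WT array 4 (median -0.085, adjusted p = 0.0264) and the cell cycle without WT array 2 (-0.19, adjusted p = 0.00654). Without Il10ra_mKO array 1 the median was -0.255 for the cell cycle and 0.19 for immediate early genes. Without Il10ra_mKO array 2 it was -0.18 for identity and -0.15 for immediate early genes. Mcm6, a replication helicase subunit, was at -0.45 ± 0.20 and Nr4a2, an immediate early transcription factor, at 0.93 ± 0.41.

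**Figure D2:**
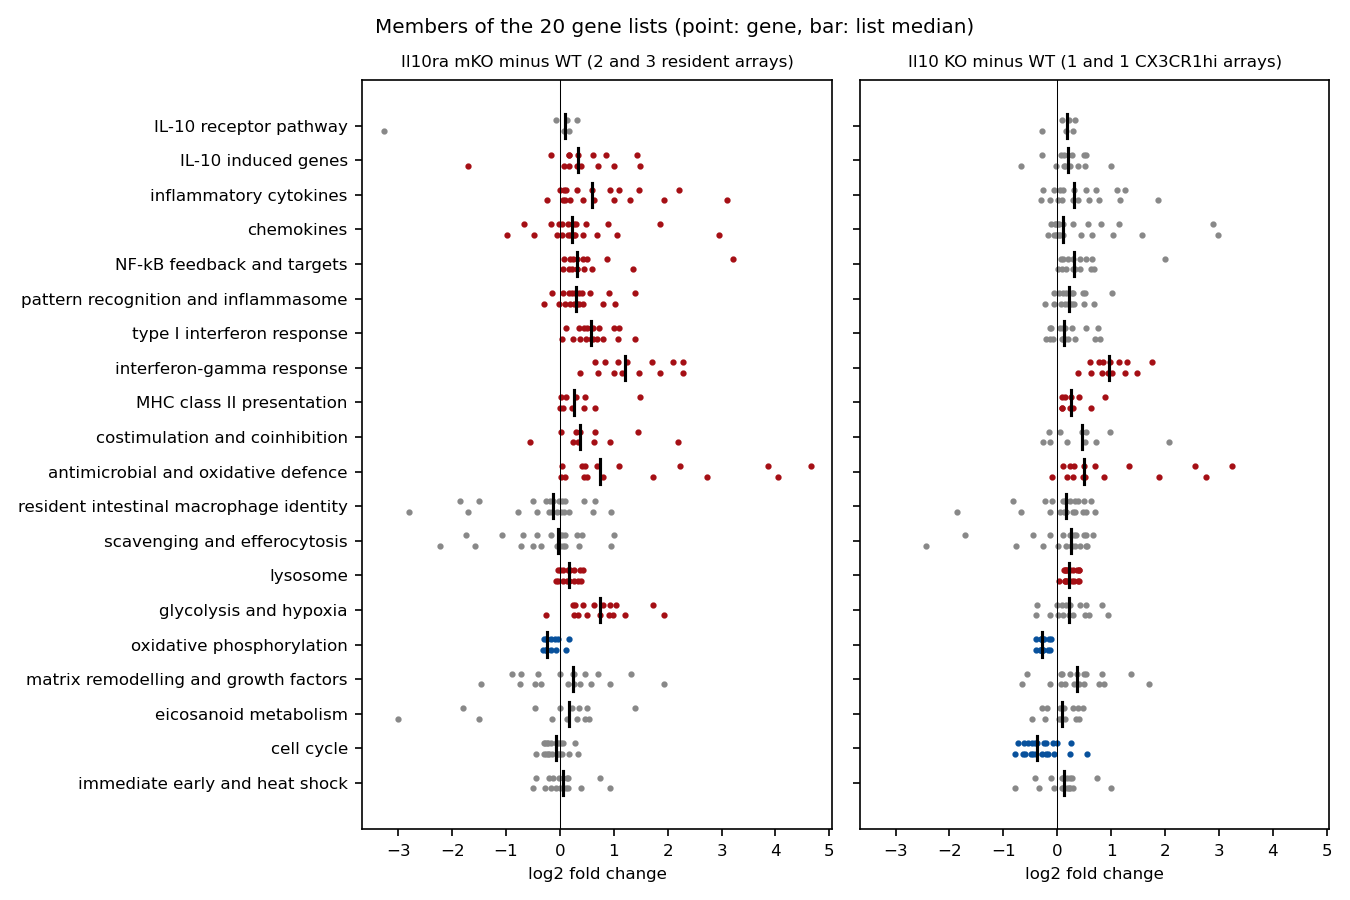
Change (log2 fold change) of each measured member of the 20 gene lists, with a point per gene, a bar at the list median, red for lists that rose by camera, blue for lists that fell and grey for the others. The median of the interferon-gamma response was 1.20 in Il10ra_mKO and 0.96 in Il10_KO, and that of oxidative phosphorylation was -0.23 and -0.27.

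Markers of other cell types moved with the Il10ra_mKO genotype as well. By camera 5 of the 12 marker lists rose and 3 fell, and 0 passed with an estimated correlation (adjusted p of 0.347 to 0.494 for the called lists) or by fry. Monocyte markers had a median of 1.22 (adjusted p = 0.00044). Adjusted over the list alone 5 of 15 rose, F10 most (3.12 ± 0.21), and 1 fell. Dendritic cell markers had a median of 0.21 (adjusted p = 0.00752), with Clec9a, a receptor of cross-presenting dendritic cells, raised by 2.91 ± 0.34 adjusted over the list alone. Medians were 0.32 for neutrophils (adjusted p = 0.00271, Ly6g at 1.28 ± 0.67), 0.40 for B and plasma cells (adjusted p = 0.0215, Ms4a1 at 1.55 ± 0.50) and 0.18 for T cells and ILC (adjusted p = 0.000795, Cd3e at 0.47 ± 0.17). Fibroblast and muscle markers fell with a median of -0.78 (adjusted p = 4.89e-08; 9 of 14 members, adjusted over the list alone), with the muscle filament gene Des at 0.01 ± 0.015. Endothelial and glial markers had a median of -0.06 (adjusted p = 0.0498, Pecam1 at 0.58 ± 0.32).

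Most of these marker calls were lost under an alternative. The neutrophil median was 0.11 without Il10ra_mKO array 1 and 0.56 without array 2, with Ly6g at 0.48 and 2.08. The neutrophil score was 6.66 and 6.23 in the Il10ra_mKO arrays and 5.99 to 6.25 in resident WT. With the brightness filter the T cell and ILC list pointed down by camera (median 0.075, adjusted p = 0.662), and the neutrophil (adjusted p = 0.531), dendritic cell (0.114), B and plasma cell (0.195) and endothelial lists (0.148) were lost. The median was 0.10 for T cells and ILC without Il10ra_mKO array 1, and 0.16 for dendritic cells without array 2. B and plasma cells were lost without WT array 2 (adjusted p = 0.173) or WT array 3 (adjusted p = 0.0581). Their median was 0.14 without Il10ra_mKO array 2 and 0.62 without Il10ra_mKO array 1. The endothelial list was lost without WT array 3 (adjusted p = 0.133) or WT array 4 (0.159), after quantile normalization (0.0753) and with no sort label (0.141). Its median was -0.03 without WT array 2. The monocyte median was 0.61 without Il10ra_mKO array 1.

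Epithelial markers fell with a median of -0.87 (adjusted p = 4.07e-05; 18 of 19 members lower, and Krt20 at 0.66 ± 0.89). Their mean level was log2 10.3 to 10.8 in resident WT and 11.3 in CX3CR1hi WT. It was 10.4 in Il10ra_mKO array 1 and 8.52 in array 2, and the epithelial median was -0.21 without array 2 and -1.69 without array 1. Sycn (7.87 and 7.57), Nxpe2 (6.07 and 6.13) and Fcrls (6.49 and 6.59) were alike in both Il10ra_mKO arrays. Eosinophil, mast cell, erythroid and housekeeping lists were not called, with medians of -0.005, 0.03, 0.002 and -0.04 (adjusted p = 0.808, 0.296, 0.808 and 0.588), and the eosinophil mean was 0.01. Their highest members were Alox15 (0.13 ± 0.088), Hdc (0.76 ± 0.27), Alas2 (0.17 ± 0.13) and Pgk1 (0.43 ± 0.24).

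**Figure D3:**
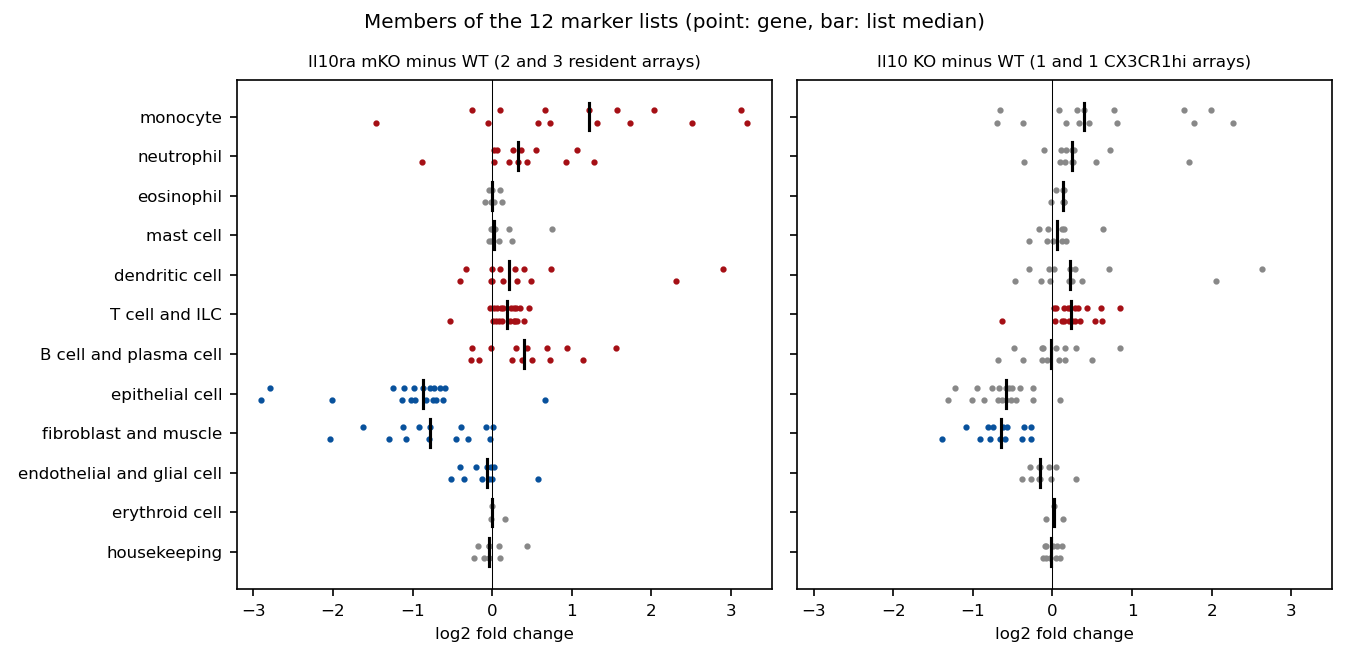
Change (log2 fold change) of each measured member of the 12 cell type marker lists, with a point per gene, a bar at the list median, red for lists that rose by camera, blue for lists that fell and grey for the others. Epithelial markers had a median of -0.87 in Il10ra_mKO and -0.59 in Il10_KO.

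The count of genes past the threshold in Il10ra_mKO rested on which arrays entered, on the scaling and on the model. It was 0 when any of the 3 resident WT arrays was left out or with runs of sample numbers as a block. With the sort label as a random block it was 125 higher and 108 lower. After quantile normalization it was 68 higher and 70 lower, and after median centring 172 higher and 249 lower. Leaving out an Il10ra_mKO array leaves 1 mutant array, so counts of such fits are not used here.

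In the array labelled Il10-deficient, Ly6i (10.7-fold, log2 3.42 ± 0.44), Procr, the endothelial protein C receptor gene (5.48-fold), and Cd300lf (4.10-fold) were higher than in the CX3CR1hi WT array, with adjusted p = 0.0303, 0.0424 and 0.0377. Ccl17 and Ccl22, chemokines that attract cells bearing CCR4, were 7.44-fold and 7.92-fold higher (adjusted p = 0.00714 and 0.0424). Chil1, a chitinase-like protein, was 15.1-fold higher (adjusted p = 0.00453). The sulfotransferase gene Sult1c2 (4.19-fold), Pck1, an enzyme of gluconeogenesis (3.76-fold), and Vsig2 (3.45-fold) were lower (adjusted p = 0.0116, 0.0454 and 0.0377), as were the pancreatic enzyme genes Cel (6.31-fold) and Try5 (5.48-fold) and Reg1 (3.67-fold; adjusted p = 0.0039, 0.0092 and 0.046). These values set 1 array against 1, with the spread taken from the other groups.

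Each of these named genes lay outside the range of all 4 WT arrays, but for several the CX3CR1hi WT array stood far from the resident WT arrays. Ccl17 was at 5.18 in it and at 7.26 to 7.46 in the resident WT arrays, beside 8.07 in the Il10-deficient array. Ccl22 was at 5.01 in it and at 6.61 to 7.20 in resident WT, beside 8.0. Chil1 was at 4.56, 5.35 to 5.36 and 8.48. Cel was at 7.10 in the CX3CR1hi WT array, 4.45 in each resident WT array and 4.44 in the Il10-deficient array, and Try5 at 7.92, 5.49 to 5.77 and 5.47. Chil1, Cel, Try5 and Reg1 lay below the brightness filter, which asks for at least 2 arrays above log2 5.86. Chil1 was above that level in the Il10-deficient array alone, and Cel, Try5 and Reg1 in the CX3CR1hi WT array alone.

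In all, 639 genes were higher and 937 lower in the array labelled Il10-deficient. Of these 1576 genes, 87.3% lay below the brightness filter and 851 had 5 resident values within 0.02 of one another. Their median absolute change was 0.18, and 22 higher and 38 lower genes differed by at least 2-fold. With an unadjusted p under 0.05 and a change of at least 2-fold, 87 were higher and 115 lower, while simulated data gave 85 false calls for this criterion. The simulation gave every array the spread of the resident arrays. If that spread is too small for the CX3CR1hi pair, 85 is too low. With the brightness filter 0 were higher and 2 lower, and without the sort label 0 passed. That filter also drops genes that are bright in a single array, so their loss does not show that they were dim there.

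Of the 20 gene lists, 4 rose and 2 fell by camera in the array labelled Il10-deficient, and none of these 6 passed with an estimated correlation (adjusted p = 0.778) or by fry. All tests of gene and marker lists in this array set 1 array against 1, with the spread taken from the resident arrays. They do not measure a spread between Il10-deficient samples. The interferon-gamma response rose with a median of 0.96 (adjusted p = 2.15e-05). Adjusted over the list alone 7 of its 14 measured members rose, and 2 over all genes tested. Iigp1 (1.75 ± 0.45), Gbp5 (1.48 ± 0.40) and Gbp7 (1.30 ± 0.30) rose adjusted over the list alone. The antimicrobial and oxidative defence list rose with a median of 0.50 (adjusted p = 0.0256; 15 of 16 members higher and 0 risen adjusted over the list alone), with Acod1 at 3.25 ± 0.67, Nos2 at 2.75 ± 0.94 and Saa3 at 2.56 ± 1.17. MHC class II presentation rose with a median of 0.25 (adjusted p = 0.0205; H2-Oa at 0.89 ± 0.68, Ciita at 0.63 ± 0.34, H2-DMa at 0.40 ± 0.085). The lysosome list rose with a median of 0.22 (adjusted p = 0.0357; Gaa at 0.41 ± 0.16, Npc2 at 0.40 ± 0.16, Ctsd at 0.40 ± 0.24). Oxidative phosphorylation fell with a median of -0.27 (adjusted p = 0.0197), with 16 of 16 members lower, among them Cox5a (-0.40 ± 0.15), Ndufs1 (-0.39 ± 0.17) and Uqcrfs1 (-0.31 ± 0.14). The cell cycle list fell with a median of -0.38 (adjusted p = 0.0197; 19 of 23 members lower), with the replication gene Mcm6 at -0.79 ± 0.32 and the mitotic genes Ccnb2 and Cdc20 at -0.73 ± 0.38 and -0.63 ± 0.17. The antimicrobial and lysosome lists were lost without WT array 2 (adjusted p = 0.0809 for both). With no sort label MHC class II (adjusted p = 0.151), oxidative phosphorylation (0.772) and the cell cycle (0.25) were lost.

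The other 14 gene lists were not called in that array, with adjusted p from 0.0764 for chemokines to 0.489 for scavenging and efferocytosis. Medians were 0.11 for chemokines, 0.32 for inflammatory cytokines, 0.32 for the NF-kB list, 0.23 for pattern recognition, 0.12 for the type I interferon response, 0.20 for IL-10 induced genes and 0.17 for resident macrophage identity. They were 0.46 for costimulation and coinhibition, 0.21 for glycolysis and hypoxia, 0.36 for matrix remodelling, 0.09 for eicosanoid metabolism, 0.19 for the IL-10 receptor pathway and 0.12 for immediate early genes. Scavenging and efferocytosis had a median of 0.26 and a mean of -0.01. Chemokines (adjusted p = 0.0398) and the NF-kB list (0.016) passed without WT array 3. Among the marker lists, T cells and ILC rose with a median of 0.23 (adjusted p = 0.0253) and fibroblasts and muscle fell with a median of -0.64 (adjusted p = 7.51e-05; 4 of 14 members, adjusted over the list alone). Neither passed with an estimated correlation (adjusted p = 0.721) or by fry. T cells and ILC were lost without WT array 2 (adjusted p = 0.0836) or WT array 4 (0.0513), with the brightness filter (0.945) and with no sort label (median -0.01, adjusted p = 0.856). Epithelial markers had a median of -0.59 and were not called (adjusted p = 0.175), though 5 of 11 alternatives called them lower. Their mean level was 10.6 in the Il10-deficient array and 11.3 in its WT partner. Monocyte markers had a median of 0.40 (adjusted p = 0.34), dendritic cell markers of 0.21 (adjusted p = 0.803) and housekeeping genes of -0.01 (adjusted p = 0.803). For mast cell and erythroid markers the median was above 0 while camera pointed down, and for B and plasma cells the median was -0.01 and the mean 0.008, none of them called.

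The effects of both mutants were then set against each other, each relative to the WT arrays of its own sort label, so that they shared no WT array. Fcrls was 8.81-fold lower in Il10ra_mKO than the change in Il10_KO would give (log2 -3.14 ± 0.14, adjusted p = 0.0112), and in Il10_KO itself it fell by 1.15 ± 0.12 (adjusted p = 0.0192). Chil1 (-3.81 ± 0.13), Ccl17 (-2.66 ± 0.19), Ermap, an erythroid membrane protein gene (-1.36 ± 0.090), and Gpr141b (-1.12 ± 0.057) also had lower effects in Il10ra_mKO (adjusted p of 0.00925, 0.0152, 0.0141 and 0.0122). The genes with the largest higher effects were the pancreatic enzyme genes Cpb1 (3.49 ± 0.073), Cpa1 (3.29 ± 0.20), Ctrb1 (3.05 ± 0.091), Ctrl (2.82 ± 0.27) and Rnase1 (2.78 ± 0.12), with adjusted p from 0.00787 for Cpb1 to 0.0232 for Ctrl. With no sort label in the model Cpb1 was at 0 and the direction turned for Cpa1 (-0.88), Ctrb1 (-2.12), Ctrl (-0.55) and Rnase1 (-0.83). Their effects in Il10ra_mKO lay between -0.11 for Rnase1 and 0.19 for Ctrl. Cpb1 was at 8.47 in the CX3CR1hi WT array and between 4.92 and 5.02 in the other 6 arrays. Ctrb1, Cpa1, Rnase1 and Ctrl were highest in the CX3CR1hi WT array (10.04, 9.64, 9.37 and 9.01). In the Il10_KO array they were at 6.93, 6.28, 6.47 and 6.39, also above the resident arrays, which reached 4.94, 5.65, 5.80 and 6.0.

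By limma the effects differed for 937 genes, 577 higher and 360 lower in Il10ra_mKO. Of these, 94.6% lay below the brightness filter and 69.7% had 5 resident values within 0.02 of one another. With the brightness filter 1 gene passed, without WT array 3 0 genes passed, and without the sort label 1 gene passed. For Il10ra the difference was -3.57 ± 0.70 (adjusted p = 0.105). No gene list and no marker list differed between the effects by camera. The lowest adjusted p among them, 0.0574, belonged to glycolysis and hypoxia (median 0.43), the type I interferon response (0.46) and resident macrophage identity (-0.22), a test added after the comparisons were fixed.

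Across the 19938 genes the log2 changes of both mutants correlated, with a Pearson r of 0.697 and a Spearman rho of 0.545. When the sort label was left out, so that both mutants shared WT arrays, the r was 0.146, below the mean of 0.258 in simulations without effects, and the rho was -0.208. With the sort label, in 100 simulated data sets without effects the mean r was -0.00151 and the highest 0.0549. The covariance was 0.0805 against -6.65e-05 in simulations. Genes are not independent replicates, so these values describe the arrays. The simulations drew noise for each gene on its own, so they hold no shift that many genes share. They cannot show how large r would be with such a shift. Medians of epithelial (-0.87 and -0.59) and of fibroblast and muscle markers (-0.78 and -0.64) were below 0 in Il10ra_mKO and in Il10_KO. Among the genes with an unadjusted p under 0.05 and a change of at least 2-fold, 56 were higher in both mutants against 0.672 for independent lists, and 40 were lower in both against 1.22. The values for independent lists treat all genes as equally able to change 2-fold, though 47.0% lay below the brightness filter. Both tests also use the same estimate of spread for a gene, so the lists are not independent even without effects. Of the 154 higher in Il10ra_mKO, 153 were higher in Il10_KO too, and of the 212 lower ones 204 were lower. The median change of the 154 genes was 1.47 in Il10ra_mKO and 1.01 in Il10_KO, and that of the 212 genes was -1.42 and -0.97. These genes were picked by their change in Il10ra_mKO, which raises its median there.

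**Figure D4:**
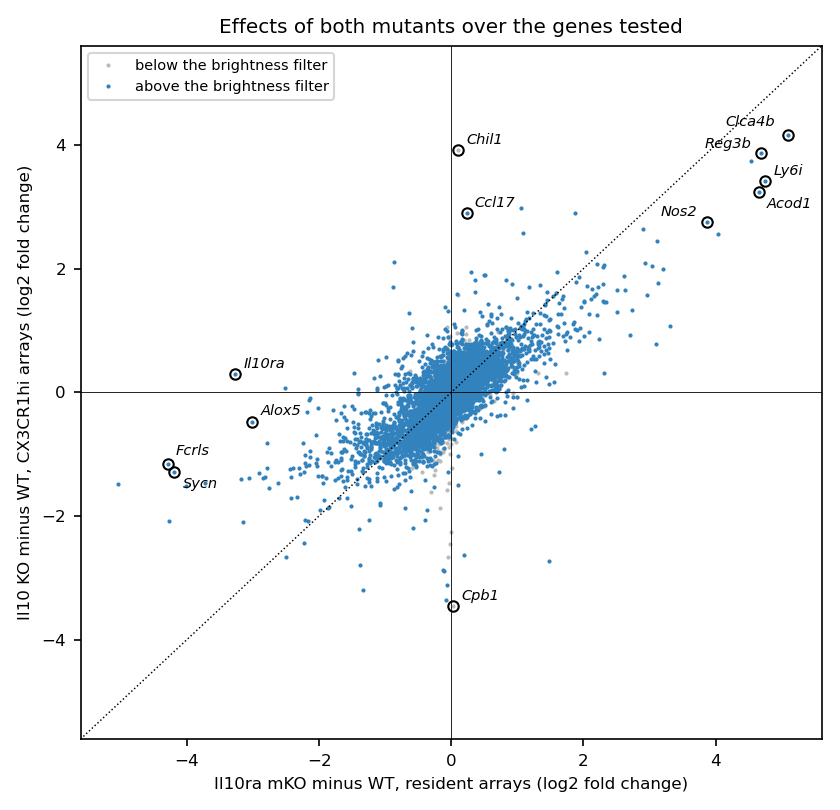
Log2 fold change of each gene tested in Il10ra_mKO (x axis, resident arrays) and in Il10_KO (y axis, CX3CR1hi arrays), grey below and blue above the brightness filter, with a dotted line where both are equal. Reg3b, Clca4b, Ly6i, Acod1 and Nos2 lie high on both axes (Ly6i at 4.75 and 3.42), while Chil1, Ccl17 and Cpb1 lie close to 0 on the x axis alone.

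The block for the sort label was checked in the WT arrays, where 1 CX3CR1hi array faced 3 resident arrays. The pancreatic enzyme genes Ctrb1 and Cpa1 were 5.18 ± 0.062 and 4.17 ± 0.13 higher on the log2 scale in the CX3CR1hi array (adjusted p = 3e-05 and 0.000143), and Ccl17 fell by 2.16 ± 0.13 (adjusted p = 0.000807). Cx3cr1 itself, chosen after its values were seen, was at 11.29 in the CX3CR1hi array and at 10.76 ± 0.078 (SD, n = 3) in the resident arrays, a difference of 0.53 ± 0.16 (adjusted p = 0.056). In all, 3894 genes were higher and 7203 lower in the CX3CR1hi array. The spread in these tests comes from the resident arrays alone. The brightness filter left 2875 higher and 446 lower, and quantile normalization 2423 and 2253. Sort label, extraction kit and array batch cannot be told apart here.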

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

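The test of pancreatic genes outside the named ones and the test of shared direction were chosen before their results were seen, and the other tests in this part after them.

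In 15 of the 38 named genes tested, and in 2 of the 32 list scores, 1 of the 4 WT arrays lay farther from the rest than Dixon's 95% limit. Chance gives about 1 in 20 for values not picked by their level, a rate that cannot be applied to these genes, since the rules that named most of them favour genes in which the CX3CR1hi WT array stands apart. In all 15 genes and in the eosinophil score it was the CX3CR1hi WT array, which carries another sort label than the other 3. That array was at 9.31 for Lmo4, 7.44 for Reps2, 5.93 for Fah, 4.44 for Fthl17f and 9.33 for B3gnt7. It was at 4.56 for Chil1, 5.17 for Ccl17, 5.21 for Gpr141b and 4.56 for the eosinophil score. It was at 7.10 for Cel, 7.92 for Try5, 8.47 for Cpb1, 9.63 for Cpa1, 10.04 for Ctrb1, 9.01 for Ctrl and 9.37 for Rnase1. The monocyte score stood apart in WT array 4, at 7.82 against 7.33 to 7.40 in the others.

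The next 10 genes were named because they passed the test of the difference between both mutant effects, so their passing adds nothing to that test. It rests on 1 Il10_KO array against 1 WT array, with the spread taken from the other groups. With the brightness filter 1 gene passed, and without WT array 3 0 genes passed. The Il10ra_mKO effect minus the Il10_KO effect was 3.49 for Cpb1, 3.29 for Cpa1, 3.05 for Ctrb1, 2.82 for Ctrl and 2.78 for Rnase1. It was -3.81 for Chil1, -3.14 for Fcrls, -2.66 for Ccl17, -1.36 for Ermap and -1.12 for Gpr141b. Outside the genes compared in the report, 205 of the 13610 probe sets without exactly 1 gene symbol passed in the array labelled Il10-deficient, against 0 in Il10ra_mKO.

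The pancreatic enzyme genes stood out in the CX3CR1hi WT array. A difference by genotype present in every WT array stays open for these genes as a set. The median of resident WT minus Il10ra_mKO was 0.0455 over 9 of them (quartiles 0.00929 and 0.0722). However, 5 of the 9 were named by a test that favours genes with little change in Il10ra_mKO. Cel, Try5 and Cela3b were not named by that test and changed by -0.05, -0.03 and -0.01 in Il10ra_mKO. For these genes resident WT showed no such difference. Clps, also of the 9 (-1.37 in Il10ra_mKO), Cela1 (-1.94) and Sycn (-4.19) go with a difference by genotype. Their mean of resident WT minus Il10ra_mKO was 2.50, but they were picked for showing it. A candidate explanation is RNA of pancreatic acinar cells in that array, which a macrophage sort would remove if it were carried by intact cells. This stays open too, because over 17 pancreatic genes outside those already seen the median of that array minus the Il10_KO array was 0.27 (quartiles 0.134 and 1.23). That lies between the bounds of 0.1 set against it and 0.5 set for it. Of the 17 genes, 8 were over 0.5 higher in that array, among them Cela2a by 1.58 and Pnliprp2 by 1.90. Others such as Spink1 (0.09) and Ptf1a (-0.16) were near 0. Genes under the brightness cut of log2 5.86 in every array, such as Ptf1a (4.38 to 4.77) and Rbpjl (4.27 to 5.11), pull the median down and can say little on this.

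Many genes passed in the array labelled Il10-deficient with small effects. A candidate explanation is that values near the floor hardly vary among the resident arrays and set too small a spread for the CX3CR1hi pair. In line with it, 87.3% of the passing genes lay below the brightness filter against 47.0% of all genes. An effect of lost IL-10 signalling shared by both mutants just met the bound of 60% set for it beforehand, with 60.2% of the passing genes having the same direction in Il10ra_mKO. It is left open because of baselines added after that result was seen: 66.3% of all genes that did not pass share direction as well, and above the brightness filter 75% of the 200 passing genes against 74.3% of the others, below it 58.1% against 56%.

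Epithelial transcripts were lower in Il10ra_mKO. Less RNA from every other cell type would lower the immune scores too. The mean of 4 immune scores minus the mean of the epithelial, fibroblast and endothelial scores rose by 1.01 (SE 0.318). It was 0.64 with Il10ra_mKO array 1 alone and 1.38 with array 2 alone. That difference holds the epithelial fall to be explained, so it cannot decide. The mean of the immune scores by themselves rose by 0.363 (SE 0.0506). It rose by 0.336 with Il10ra_mKO array 1 alone and by 0.391 with array 2 alone. With the brightness filter the T cell list pointed down by camera and the neutrophil, dendritic cell and B cell lists were lost. A lost call is not a fall, however. Over 13 alternatives the lowest medians were 0.075 for T cells, 0.109 for neutrophils, 0.156 for dendritic cells and 0.141 for B cells. For these 4 immune lists the values argue against less RNA from every other cell type. Less epithelial RNA in the sorted cells, which a macrophage sort would remove if it were carried by intact cells, may account for the fall itself, since 33 epithelial genes outside the fixed list had a median change of -0.663 and 30 of them were lower, mostly in Il10ra_mKO array 2. It cannot account for Reg3b, Reg3g and Clca4b, picked after their values were seen, whose mean change was 4.78 (SE 1.14). A change in the epithelium around the macrophages, named by no label, was not tested.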

How the results depend on the processing

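Tests chosen after the results were seen are those without the genes flat over the resident arrays, those that join the brightness filter with a 2-fold change, and all alternatives for the sort labels; the others were planned. No paired analysis was possible because the replicate numbers come from the order of the series and pair no samples, while a blocked analysis was possible and was run. Its blocks were runs of neighbouring sample numbers in the titles, of which 2 hold both Il10ra_mKO and WT arrays: 0 genes fell in Il10ra_mKO, with Fcrls at -4.28 (adjusted p = 0.213). Il10ra_mKO and Il10_KO hold fewer than 3 arrays, so no count over other splits of the samples was made. Of 121 single-gene results 108 kept their direction under every alternative run and 26 also their side of the threshold, and of 64 single-list results 61 and 17. The settings of single genes gave 1916 values on the same side, 140 that no longer passed, 327 that newly passed and 18 of the other sign. For single lists these were 639, 86, 36 and 3. Unless stated, the cause was not tested. Signal over background limits the dim genes, where RMA leaves little spread.

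Counts below are higher then lower. In Il10ra_mKO the main count was 0 and 1. Without the sort label it was 33 and 37, with it as a random block 125 and 108, without the variance trend 1 and 3, with the brightness filter 5 and 7, after quantile normalization 68 and 70, and after median centring 172 and 249. At an adjusted p under 0.1 it was 3 and 4, at an unadjusted p with 2-fold change 154 and 212, and with that and the brightness filter 161 and 228. Without flat genes it was 19 and 12. Fewer genes were tested with the filters (10558) and without flat genes (18298). Leaving out an array gave 0 to 194 higher and 0 to 174 lower. The upper ends of these ranges come from fits without an Il10ra_mKO array, which leave 1 mutant array, so they are not used here. Leaving out any WT array or the Il10_KO array gave 0 higher and 0 or 1 lower. Fcrls ranged from -4.34 to -4.25 over 21 alternatives, with adjusted p from 1.1e-05 to 0.553, and no longer passed in 4.

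In Il10_KO the main count was 639 and 937, 40.5% higher. Without the sort label it was 0 and 0, with a random block 1 and 0, without the trend 307 and 451, with the robust variance 395 higher, with the brightness filter 0 and 2. After quantile normalization it was 2 and 15 (11.8% higher), after median centring 37 and 92 (28.7% higher). With every probe set it was 336 and 539, at an adjusted p under 0.1 1035 higher, by p and 2-fold 87 and 115, with the brightness filter as well 87 and 106, and without flat genes 9 and 16. Without the sort label and without the CX3CR1hi WT array it was 4555 and 7235, since the array then faces another sort label. Leaving out an array gave 187 to 1255 higher and 372 to 1533 lower, lowest without WT array 3.

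For the difference of the effects the main count was 577 and 360, 61.6% higher. Without the sort label it was 0 and 1, with a random block 0 and 2, without the trend 19 and 11, with the robust variance 252 and 135, with the brightness filter 1 and 0. After quantile normalization it was 9 and 2 (81.8% higher), after median centring 14 and 6. With every probe set it was 55 and 21, at an adjusted p under 0.1 590 lower, by p and 2-fold 25 and 42, with the brightness filter as well 17 and 47, and without flat genes 8 and 2. Leaving out an array gave 0 to 1284 higher and 0 to 916 lower, with 0 genes without WT array 3. The upper ends of these ranges come from the fit without Il10ra_mKO array 2, which leaves 1 array in each mutant group, so they are not used here. For the sort labels (3894 and 7203) the brightness filter left 446 lower, and quantile normalization gave 2423 and 2253 (51.8% higher against 35.1% in the main count).

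Of gene lists in Il10ra_mKO (12 up, 1 down), 0 and 0 passed with an estimated correlation, 3 and 0 by fry, and without the sort label 4 were down. In Il10_KO (4 up, 2 down) it was 0 and 0 with an estimated correlation, 0 and 0 by fry, 13 and 0 without the sort label, and 11 up after quantile normalization. Of marker lists in Il10ra_mKO (5 up, 3 down) 0 and 0 passed with an estimated correlation and 0 and 0 by fry, and with the brightness filter 1 was up. In Il10_KO (1 up, 1 down) it was 0 and 0 with an estimated correlation, 0 and 0 by fry, 3 down on ranks, 0 up without the sort label, 0 and 2 with the brightness filter, and 2 down after quantile normalization. Leaving out an array gave 8 (without Il10ra_mKO array 2) to 13 (without array 1) gene lists up and 1 to 2 down in Il10ra_mKO and 2 to 6 up in Il10_KO, and marker lists of 3 to 5 up and 1 to 3 down in Il10ra_mKO and 0 to 1 up and 1 to 2 down in Il10_KO. The correlation of the effects was 0.146 (Pearson) and -0.208 (Spearman) without the sort label, where both mutants share WT arrays and simulations without effects gave 0.258. There the covariance was 0.0268 against a simulated 0.0218. With the brightness filter the Spearman rho was 0.673, and leaving out an array gave 0.53 to 0.716 (Pearson) and 0.376 to 0.569 (Spearman).

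The direction turned in these results. Without the sort label Il10 was at -0.052 and Des at -0.001 in Il10ra_mKO, and Il10 at 0.38, Ndufs1 at 0.22 and Uqcrfs1 at 0.44 in Il10_KO. For the difference of the effects Il10 was at -0.43, Cpa1 at -0.88, Ctrb1 at -2.12, Ctrl at -0.55 and Rnase1 at -0.83. Without the sort label and the CX3CR1hi WT array, Il10 was at 0.60, Ndufs1 at 0.42, Uqcrfs1 at 0.69 and Mcm6 at 0.063 in Il10_KO. With the brightness filter the T cell and ILC list had a median of 0.075 and camera pointed down. Leaving out an array gave, in Il10ra_mKO, -0.025 to 0.525 for Il10, -0.004 to 0.26 for Alox15, -0.57 to 1.90 for Krt20 and 0 to 0.016 for Des. List medians ranged there from 0.038 to 0.275 for the lysosome, where camera pointed down without Il10ra_mKO array 2, and from -0.15 to 0.19 for immediate early and heat shock genes.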

Other observations

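The test of Reg3b, Reg3g and Clca4b was chosen only after its result was seen, and the other values in this part were not tested.

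Reg3b and Reg3g, antibacterial lectins of the gut epithelium, and Clca4b, a gene of the calcium-activated chloride channel regulator family, were high in all 3 mutant arrays. They were picked after their values were seen. In Il10ra_mKO against resident WT the log2 difference was 4.69 ± 1.26 (SE) for Reg3b, 4.54 ± 1.19 for Reg3g and 5.10 ± 0.66 for Clca4b. Reg3b was at 13.27 and 9.94 in the Il10ra_mKO arrays and at 6.21 to 7.96 in resident WT. In the array labelled Il10-deficient Reg3b was at 11.98, Reg3g at 11.74 and Clca4b at 9.92, against 8.10, 8.0 and 5.75 in the CX3CR1hi WT array.

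Levels of different genes cannot be ranked on an array, so each epithelial transcript here is set only against itself in other arrays. Lypd8, a secreted protein of colonic epithelium, lay between 12.94 and 13.60 in the 7 arrays. Muc3, a membrane mucin, was at 11.76 to 13.03 in the WT arrays, 12.45 in the array labelled Il10-deficient and 10.94 and 9.999 in the Il10ra_mKO arrays, and it was 1.58 ± 0.39 lower in Il10ra_mKO than in resident WT. Mep1a, a brush border protease, was at 8.09 to 9.27 in resident WT and 6.79 and 5.81 in Il10ra_mKO. Cdx2, an intestinal transcription factor, was at 8.46 in Il10ra_mKO array 1, inside the WT range of 8.25 to 8.95, and at 5.86 in array 2. Slc51b, a bile acid transporter subunit, went the other way in array 1, at 8.95 against 6.74 to 7.14 in resident WT.

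Flat values lay mostly near the floor. The 5 resident values lay within 0.02 for 1640 genes (8.23%), and 86.3% of those lay below the brightness filter. The 2 CX3CR1hi values lay within 0.02 for 8.61% of genes and the 2 Il10ra_mKO values for 29.3%. The CX3CR1hi arrays differ in genotype and the Il10ra_mKO arrays do not, and the first share spans 5 arrays. The 3 shares are therefore not alike in kind.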
